A study of Mus musculus with 36 samples.

How the data were processed

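The series measured messenger RNA in 2 mouse skeletal muscles, the slow soleus and the fast extensor digitorum longus (EDL). The muscles came from mice in which genes for the estrogen-related receptors (ERRs), orphan nuclear receptors that regulate oxidative metabolism, were deleted in muscle. Per the labels' protocols, floxed mice on the C57BL/6JBom background were crossed to mice expressing Cre recombinase from the human alpha-skeletal actin promoter, and muscles were taken from 1-year-old males kept at about 22 °C with 12 h of light. Total RNA (400 ng) was made into directional libraries with 10 PCR cycles, per the labels' protocols. There were 3 deletion classes (ERRalpha, ERRbeta with ERRgamma, ERRalpha with ERRgamma), each with its own wild-type littermates, giving 36 libraries in 12 groups of 3.

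The deposited table holds log2 signals for 45802 gene rows, and its name says that the authors took logs and quantile normalized the signals. The submitters' processing notes name Partek 6.6 and the genome builds GRCm38.p6 and mm10. The aligner, the counting method and the unit before the log are not given in the sources used here. The base of the log was read from the values. Among 328 genes with 1 annotated transcript and a value in 8 to 20 libraries, 882 of 4097 values lay 0.9 to 1.3 above the gene's lowest value and 354 lay 1.5 to 1.8 above it, as 2 and 3 reads would on a log2 scale, while 39 lay 0.4 to 0.8 above it. The lowest values fell with exon length (slope -0.85 ± 0.038 per doubling, SE, 302 genes detected in 4 to 10 libraries), as in a signal scaled by length. An empty cell was read as not detected. Quantile normalization removed the read totals, so the depth of each library is unknown. The nearest measure of it was the number of genes detected, 13689 to 14975 per library. The quantiles were equal over the detected genes of each library, so libraries with more detected genes had higher values at the genes all share, with a mean of 1.70 to 2.08 over the kept genes detected in every library.

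Columns were matched to groups by the muscle, class letters and Cre mark in their names. The mark FXp was read as floxed with Cre (knockout) and FX- as floxed without Cre (wild type). The EDL columns of the ERRalpha class carry no class letter and were assigned through a number, read as the animal's, that they share with soleus columns of that class. The direction of every change rests on this reading, and "knockout-labelled" is used throughout. Columns carry no replicate number, so libraries are numbered in column order as names only. The 3 animals of a group are biological replicates per the series design.

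Of the rows, 27904 held no value and 27 had symbols turned into dates, 25 of these with values, which were left out. The 13 protein genes of the mitochondrial genome are listed without a value and were not analysed. Genes were kept where their mean over all libraries, with missing values counted at the lowest value of the table (-8.21), exceeded the 25th percentile of the gene means (-5.24), which left 13404 of 17873 genes, 88.9% of them with a value in every library. Missing values stayed missing in the tests, and no pseudocount was added.

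Differences were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on all 36 libraries with 1 mean per group and a shared estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Changes are knockout-labelled minus wild type on the log2 scale, given ± SE with n = 3 libraries per group unless said otherwise. There were 16 contrasts: 6 of knockout-labelled against wild type, wild-type soleus against EDL, the difference of each class's change between muscles, and the differences between classes within a muscle. A list was tested with camera at a preset correlation of 0.01 on genes complete in all libraries, Benjamini-Hochberg over the 29 lists with at least 5 genes kept. Camera with an estimated correlation and fry were alternatives.

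Chosen before the data were examined were the groups, contrasts, 30 gene lists (of which 29 could be tested), alternatives and the rule for named genes. Lists covered the respiratory chain complexes, the tricarboxylic acid (TCA) cycle, fatty acid oxidation, branched-chain amino acid and ketone catabolism, glycolysis, mitochondrial ribosome, import and dynamics, chaperones and proteases, regulators of biogenesis, antioxidant and integrated stress genes. They also covered slow and fast contractile, denervation and atrophy, satellite cell, angiogenic, immediate early, clock and ribosomal protein genes, and markers of endothelial, smooth muscle, fibroblast, leukocyte, fat, Schwann and red blood cells. The rule named Esrra, Esrrb and Esrrg, and the 6 largest rises and falls among called genes at or above the median level whose knockout-labelled and wild-type libraries did not overlap. It added up to 3 called members of each list, or the member with the lowest p where none was called, and the 5 genes with the lowest adjusted p for differences between muscles or classes. Where other genes are named, that is said.

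Alternatives were a stricter filter and none, recentring each library on the trimmed mean (30% off each end) of its log ratios, a pseudocount of 0.0264 on the linear scale, only the samples of a contrast, no trend, a 1.5-fold minimum and leaving out each library. With the number in the column names read as the animal's, which the labels do not state, 14 of 22 animals gave both muscles. Deviations from the group means of the 2 muscles of an animal correlated with r of -0.068 to 0.32 across genes (median 0.097 over 14 pairs). The median was -0.052 over 40 other pairs. Deviations within a group sum to 0, which ties the other pairs to the first ones, so they are no independent baseline. The animal was added as a random block after seeing the data (consensus correlation 0.137).

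Replicate libraries correlated across genes with r of 0.947 to 0.989. The lowest values, 0.947 to 0.975, were those of knockout-labelled soleus of the ERRbeta/ERRgamma class, and all pairs of other groups lay at 0.980 or above. None held the values of another: of 36 pairs, none shared more than 2 identical values among 11932 genes. The test was checked on simulated data for the EDL ERRalpha comparison over 11914 genes with 50 genes changed at each size. It recovered 42% at a log2 change of 0.5, 72% at 1, 96% at 2 and 100% at 4, and 3.73% of its 161 calls were false. The simulated noise was normal, independent between genes and equal in all groups, with no missing values, so the real libraries may give other rates. Gene positions come from GENCODE M21 (GRCm38), which held 95.4% of the symbols with a value. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.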

Results

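RNA was profiled in soleus, rich in slow oxidative fibres, and in EDL, rich in fast fibres, of mice labelled as lacking ERRalpha, ERRbeta with ERRgamma, or ERRalpha with ERRgamma in muscle, with 3 knockout-labelled and 3 wild-type libraries per muscle and class (36 in all). Between 13689 and 14975 genes were detected per library, the only trace of depth left in the quantile-normalized log2 signals. Of 13404 genes kept, 13270 to 13385 could be tested per comparison of 2 groups or muscles.

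The receptor genes were examined first, since the labels name them as the deleted genes. On GRCm38, Esrra (chromosome 19, 6910977 to 6921813, minus strand) encodes ERRalpha, Esrrb (chromosome 12, 86361117 to 86521628, plus strand) ERRbeta, and Esrrg (chromosome 1, 187608791 to 188214885, plus strand) ERRgamma. In EDL of the ERRalpha/ERRgamma class, Esrra was 5.33 ± 0.061 in wild-type and 3.09 ± 0.17 in knockout-labelled libraries (SD, n = 3 each), a change of -2.23 ± 0.12, and in soleus it changed by -0.57 ± 0.12. In the ERRalpha class Esrra was not called, with 5.20 ± 0.083 against 5.01 ± 0.084 in EDL (-0.19 ± 0.12) and 5.52 ± 0.30 against 5.85 ± 0.11 in soleus (0.33 ± 0.12). Esrrg was higher in 3 comparisons that name ERRgamma as deleted: 1.09 ± 0.15 in soleus of the ERRbeta/ERRgamma class, 1.21 ± 0.15 in soleus and 0.51 ± 0.15 in EDL of the ERRalpha/ERRgamma class. The last of these was not called after recentring, and 0.48 ± 0.15 in EDL of the ERRbeta/ERRgamma class was not called. It also rose in EDL of the ERRalpha class (0.61 ± 0.15), which does not name ERRgamma, and was not called in its soleus (0.36 ± 0.15). Esrrb was not called in the class that names it (-0.18 ± 0.21 in EDL, 0.28 ± 0.21 in soleus), and it fell in EDL of the ERRalpha/ERRgamma class (-1.60 ± 0.21). Signals over a whole gene need not show the loss of 1 exon, so these values do not check most labels. Where a deleted gene was higher, they neither bear out its label nor contradict it.

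**Figure D1:**
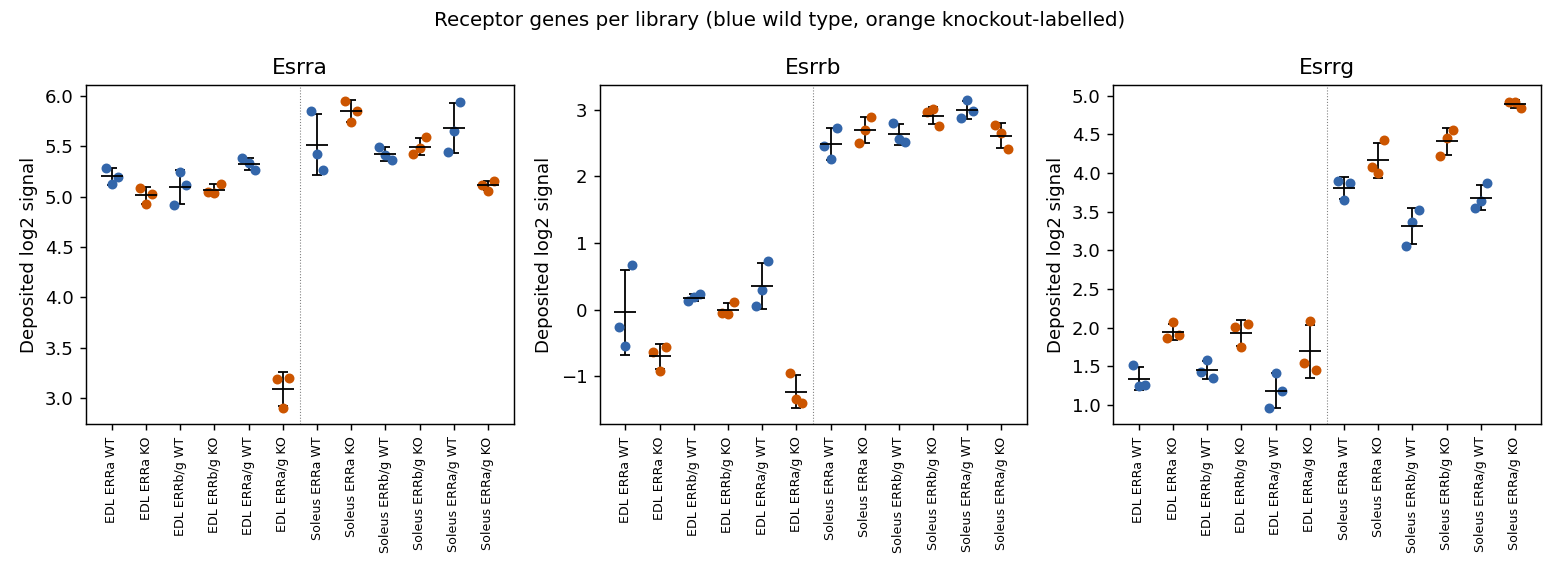
Deposited log2 signal (vertical axis) of Esrra, Esrrb and Esrrg in each of 36 libraries (points) by muscle, class and genotype label (horizontal axis), with group means and SD (bars, n = 3). Esrra stood at 3.09 ± 0.17 in knockout-labelled EDL of the ERRalpha/ERRgamma class and at 5.33 ± 0.061 in its wild types, while Esrrg rose to 4.89 ± 0.048 in knockout-labelled soleus of that class.

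Wild-type soleus was compared with wild-type EDL over 9 libraries each to set the baseline. All 15 slow contractile genes were higher in soleus, with a median difference of 6.20: the slow myosin heavy chain Myh7 by 9.77 ± 0.54, and the slow troponins Tnni1 by 8.36 ± 0.27, Tnnt1 by 7.99 ± 0.24 and Tnnc1 by 8.79 ± 0.30. The myosin light chains Myl3 and Myl2 were higher by 9.27 ± 0.32 and 7.36 ± 0.36. Of 15 fast contractile genes, 14 were lower and 1 higher, including the fast myosin heavy chain Myh4 (-5.59 ± 0.62), the calcium buffer parvalbumin, Pvalb (-5.12 ± 0.26), the fast actinin Actn3 (-5.07 ± 0.33) and the myosin-binding protein Mybpc2 (-4.41 ± 0.25). All 25 fatty acid oxidation genes were higher (median 0.98), and 15 of 18 glycolysis genes were lower and 2 higher (median -1.38). Outside the lists Dkk3, a secreted Wnt modulator, was lower by 7.79 ± 0.35 and the growth inhibitor myostatin, Mstn, by 4.29 ± 0.26. Complex I genes went both ways (10 higher, 9 lower of 36). Over all 76 respiratory chain genes, complex I included, 30 were higher and 11 lower (median 0.074). Esrrb was higher in soleus by 2.54 ± 0.12, Esrrg by 2.28 ± 0.086 and Esrra by 0.33 ± 0.067. Adjusted over the list alone the counts were the same for the 5 lists just given. Of 57 mitochondrial ribosome genes 38 were higher and 1 lower (38 and 1 adjusted over the list alone). Camera called 5 lists. The slow contractile list held with an estimated correlation (adjusted p = 1.02e-15 preset, adjusted p = 0.036 with an estimated correlation). Fatty acid oxidation (adjusted p = 0.233 with an estimated correlation), glycolysis (adjusted p = 0.138 with an estimated correlation), fast contractile (adjusted p = 0.164 with an estimated correlation) and mitochondrial ribosome (adjusted p = 0.606 with an estimated correlation) did not. In all, 7218 of 13270 genes were called (4089 higher, 3129 lower).

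In EDL the ERRalpha class was compared with its wild types. Nuclear genes of the respiratory chain fell by a modest amount: 22 of 36 subunits of complex I (median -0.32), 6 of 14 genes of complexes II and III with cytochrome c (-0.24), 8 of 11 of cytochrome c oxidase (-0.33) and 7 of 15 of ATP synthase (-0.28), and none rose. Examples were Ndufa8 (-0.58 ± 0.066), Ndufb7 (-0.60 ± 0.073), Uqcrq (-0.69 ± 0.083), cytochrome c, Cycs (-0.60 ± 0.088), Cox4i1 (-0.62 ± 0.083) and Atp5e (-0.48 ± 0.085). Adjusted over the list alone, 33, 8, 9 and 10 fell in these lists, whose camera calls held with an estimated correlation. The antioxidant list also held (3 of 22 fell, and 3 adjusted over the list alone), with Sod2, the mitochondrial superoxide dismutase, at -0.70 ± 0.089, Prdx6 at -0.33 ± 0.068 and Prdx5 at -0.42 ± 0.087. In the TCA cycle 8 of 23 genes fell (11 fell adjusted over the list alone), with Pdha1 of pyruvate dehydrogenase at -0.40 ± 0.076, but the list's call was lost (adjusted p = 0.229 with an estimated correlation). No fatty acid oxidation gene of 25 was called, nor adjusted over the list alone (median -0.16, adjusted p = 0.651 with an estimated correlation). Import and dynamics genes fell in 5 of 28 (1 rose and 8 fell adjusted over the list alone, adjusted p = 0.165 with an estimated correlation), led by the outer membrane fusion gene Mfn1 (-0.75 ± 0.084). Camera calls were also lost for the mitochondrial ribosome (5 of 57 fell, 1 rose and 7 fell adjusted over the list alone, adjusted p = 0.636 with an estimated correlation) and for branched-chain and ketone catabolism (0 of 19, 1 rose and 4 fell adjusted over the list alone, adjusted p = 0.636 with an estimated correlation). The same held for ribosomal proteins (1 of 48 rose, 1 rose adjusted over the list alone, adjusted p = 0.888 with an estimated correlation). Fibroblast genes (0 of 21, median -0.33, adjusted p = 0.819 with an estimated correlation) and red blood cell genes (0 of 5, median -1.01, adjusted p = 0.636 with an estimated correlation) lost theirs too.

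Large single changes in that comparison lay outside these lists. Phkb (chromosome 8, 85840959 to 86061376, plus strand), the beta subunit of the kinase that activates glycogen phosphorylase, rose by 2.42 ± 0.15, from 5.86 ± 0.13 to 8.28 ± 0.22 (SD, n = 3 each, adjusted p = 5.85e-12). Car3, a carbonic anhydrase of muscle and fat, rose by 2.26 ± 0.28, Gamt, which makes creatine, by 2.00 ± 0.43, and the G-protein regulator Rgs2 by 1.72 ± 0.25. The interferon regulatory factor Irf5 rose by 1.71 ± 0.44 and the small heat shock gene Hspb7 by 1.64 ± 0.33. The falls were Amy1, an amylase (-2.01 ± 0.23), Maob, a monoamine oxidase (-1.35 ± 0.22), Amd1 of polyamine synthesis (-1.23 ± 0.33), Slco3a1, an organic anion carrier (-1.08 ± 0.14), and Gmnn, a replication inhibitor (-1.04 ± 0.22). BC048679 also fell (-2.15 ± 0.41), but its call ended when missing values were set to the lowest value. Of 23 denervation and atrophy genes 3 rose (4 adjusted over the list alone): the acetylcholine receptor subunit Chrnb1 (0.84 ± 0.18), the cell cycle inhibitor Cdkn1a (1.31 ± 0.35) and the synaptic kinase Musk (0.91 ± 0.26, not called after recentring). Camera did not call that list (adjusted p = 0.0728). Of the slow contractile genes 1 of 15 rose, Myoz2 (1.32 ± 0.29), and adjusted over the list alone 3 rose and 1 fell. In all, 436 genes were called (242 higher, 194 lower). Fitting the 6 libraries alone gave 201, and leaving out 1 library gave 225 (without knockout-labelled replicate 3) to 303.

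In EDL of the ERRbeta/ERRgamma class few genes changed, 29 in all (8 higher, 21 lower; 953 at an unadjusted p under 0.05), and the named genes that fell most were myosin genes. The slow myosin light chains Myl2 (-4.21 ± 0.63) and Myl3 (-2.67 ± 0.56) fell, as did Myh2, the heavy chain of IIA fibres (-1.97 ± 0.35), and Myom3, an M-band protein (-1.21 ± 0.23). Lpl, lipoprotein lipase, fell by 1.11 ± 0.19, Amy1 by 1.38 ± 0.23 and Idh2, the mitochondrial isocitrate dehydrogenase using NADP, by 1.10 ± 0.20. Car3 (1.74 ± 0.28), the Notch pathway ligase Mib1 (0.89 ± 0.16), the splicing gene Snrpb2 (0.50 ± 0.10) and the sulfhydryl oxidase gene Gfer (0.43 ± 0.088) rose, the last 2 not called after recentring. Slow contractile genes fell in 2 of 15 (7 fell adjusted over the list alone, median -0.74, adjusted p = 0.0693 with an estimated correlation). Fatty acid oxidation genes fell in 1 of 25, Lpl, and adjusted over the list alone 11 fell (median -0.32, adjusted p = 0.163 with an estimated correlation). In other lists camera called, Idh2 was the only gene called of 23 in the TCA cycle (adjusted p = 0.764 with an estimated correlation). None was called for branched-chain and ketone catabolism (adjusted p = 0.385 with an estimated correlation) or chaperones and proteases (adjusted p = 0.163 with an estimated correlation). Nor was any for ribosomal proteins (adjusted p = 0.764 with an estimated correlation), endothelium (adjusted p = 0.764 with an estimated correlation) or smooth muscle (adjusted p = 0.629 with an estimated correlation). Counts adjusted over each list alone were 1 for the TCA cycle and 0 for the others. No gene of the 4 respiratory chain lists was called, with medians of -0.057 to 0.00014, and 0 were called adjusted over each list alone. A fit of the 6 libraries alone called 4 genes (3 of them among the 29), and leaving out 1 library gave 11 (10 among the 29, without wild-type replicate 2) to 25 (21 among the 29).

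In EDL of the ERRalpha/ERRgamma class nearly the whole oxidative set fell. Of complex I subunits 35 of 36 fell (median -1.03), of complexes II and III 14 of 14 (-1.60), of cytochrome c oxidase 10 of 11 (-1.43), and of ATP synthase 15 of 15 (-1.28). So did 23 of 23 genes of the TCA cycle (-1.33), 23 of 25 of fatty acid oxidation (-1.10) and 18 of 19 of branched-chain amino acid and ketone catabolism (-0.79). Adjusted over the list alone the counts were 36, 14, 10, 15, 23, 25 and 19, none rose, and all 7 camera calls held with an estimated correlation. Cyc1, cytochrome c1, fell by 2.14 ± 0.085, the succinate dehydrogenase subunit Sdhb by 2.07 ± 0.079, Ndufb5 of complex I by 2.02 ± 0.083, and Atp5b of ATP synthase by 2.02 ± 0.091. The isocitrate dehydrogenase subunit Idh3b fell by 2.01 ± 0.067 and the thiolase Acaa2 by 1.70 ± 0.13. Chchd10 (chromosome 10, 75933130 to 75937747, plus strand), a protein of the mitochondrial intermembrane space, fell by 2.82 ± 0.089 (adjusted p = 1.68e-19). Mitochondrial ribosome genes fell in 31 of 57 (Mrpl12, -1.57 ± 0.10), import and dynamics genes in 22 of 28 (Mfn1, -1.63 ± 0.084), and chaperones and proteases in 9 of 12 (Hspa9, -1.14 ± 0.081). Adjusted over the list alone, 38 fell, 1 rose and 24 fell, and 1 rose and 9 fell, and all 3 calls held with an estimated correlation. Of antioxidant genes 8 of 22 fell and 4 rose, with 8 and 6 adjusted over the list alone. The mitochondrial members Sod2 (-1.65 ± 0.089), Txn2 (-0.87 ± 0.068) and Prdx3 (-0.97 ± 0.08) were among the falls, and the call held with an estimated correlation. Glycolysis genes were not called (0 of 18, and 0 adjusted over the list alone).

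Members of other groups rose in the same muscle. Ribosomal protein genes rose in 46 of 48 (46 adjusted over the list alone, median 0.50, adjusted p = 0.0715 with an estimated correlation), led by Rpl4 (0.84 ± 0.064). Genes matched to them for level and exon length had a median of 0.35. Of slow contractile genes 8 of 15 rose and 2 fell (8 and 2 adjusted over the list alone). The slow heavy chain Myh7 rose by 3.55 ± 0.94, Csrp3, a Z-disc protein, by 2.58 ± 0.66, the calcium pump inhibitor sarcolipin, Sln, by 2.45 ± 0.62 and the slow troponin Tnnc1 by 2.28 ± 0.52. The falls were myoglobin, Mb (-1.01 ± 0.17), and the calcium store protein Casq2 (-1.44 ± 0.32). Camera did not call this list (adjusted p = 0.239). Denervation and atrophy genes rose in 8 of 23 (11 rose adjusted over the list alone, adjusted p = 0.119 with an estimated correlation), among them Chrnb1 (1.11 ± 0.18), the ubiquitin ligase Fbxo32 (0.92 ± 0.18) and the myogenic factor Myog (2.20 ± 0.43). Satellite cell and myogenic genes rose in 4 of 10 (6 rose adjusted over the list alone), a call that held with an estimated correlation, with Myf6 at 0.99 ± 0.16 and Myog shared with the list before. Gamt (3.03 ± 0.43), Car3 (2.49 ± 0.28) and Phkb (2.47 ± 0.15) were among the largest rises. The largest falls also held Gnb5, a G-protein subunit (-2.80 ± 0.22), Ephx2, an epoxide hydrolase (-2.56 ± 0.19), Clybl, a mitochondrial lyase (-2.54 ± 0.21), Kcng4, a potassium channel subunit (-2.51 ± 0.46), and BC048679 (-3.21 ± 0.58). Fibroblast and leukocyte markers were not called in EDL (0 of 21 and 0 of 18, medians 0.12 and 0.019). In all, 2416 genes were called, 1487 higher and 929 lower. The median of all genes was 0.13 above 0, and after recentring the split was 819 higher and 1162 lower.

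**Figure D2:**
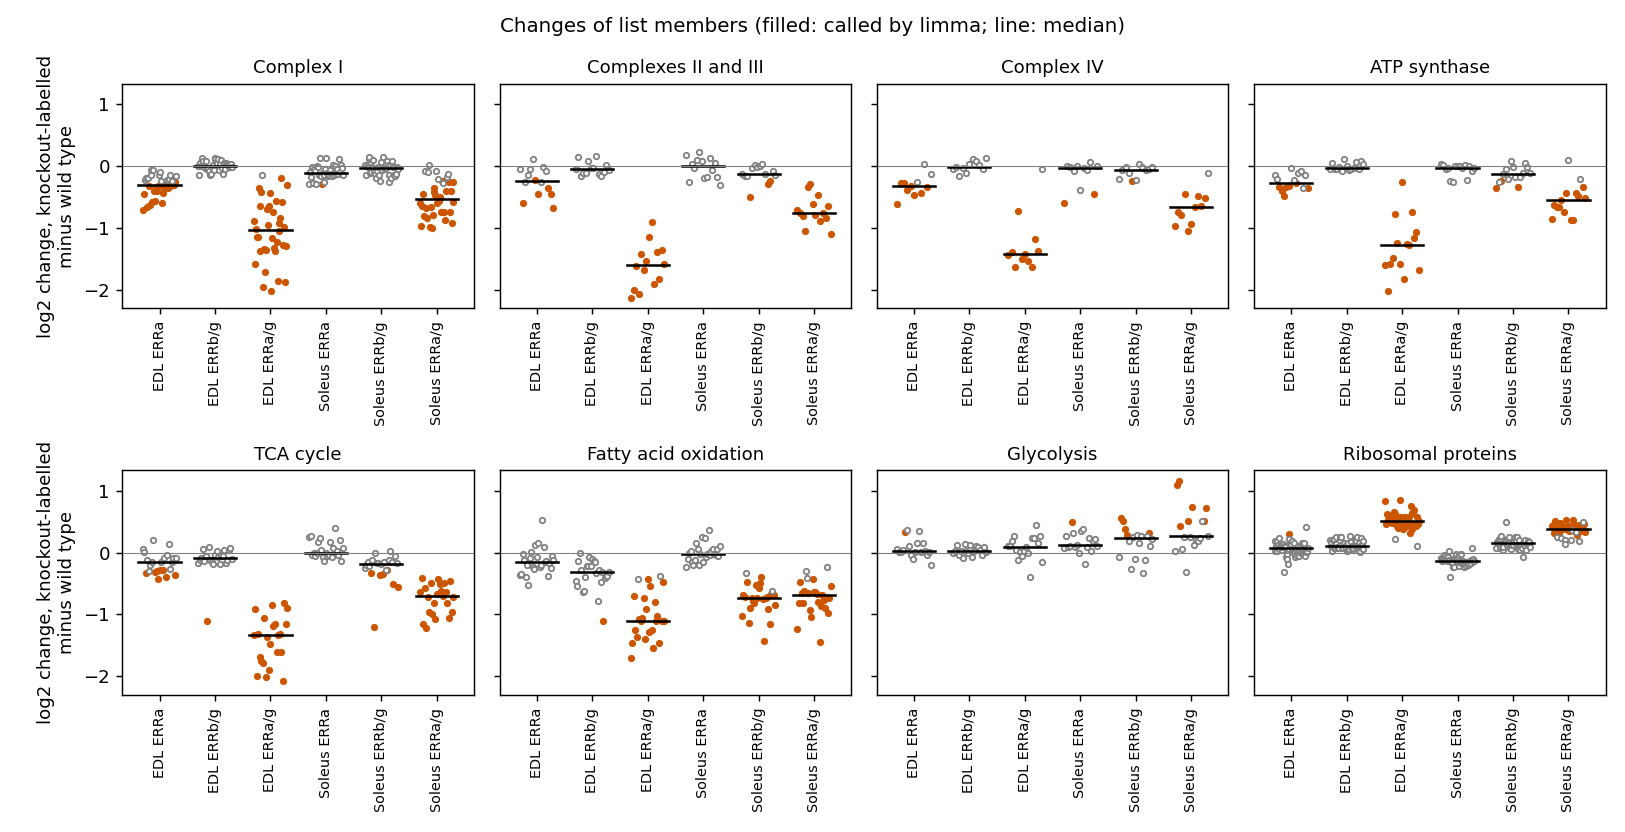
Log2 change of each list member (points, vertical axis) in the 6 knockout comparisons (horizontal axis, n = 3 against 3), filled where limma called the gene, with the list median as a line. Complexes II and III lay at -1.60 in EDL and -0.76 in soleus of the ERRalpha/ERRgamma class, and fatty acid oxidation at -0.73 in soleus of the ERRbeta/ERRgamma class. Ribosomal protein medians in EDL and soleus of the first class were 0.50 and 0.39 as deposited and 0.40 and 0.31 after recentring.

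In soleus of the ERRalpha class few oxidative genes changed. Cytochrome c oxidase genes fell in 2 of 11, Cox4i1 (-0.61 ± 0.083) and Cox7c (-0.46 ± 0.10), and 3 fell adjusted over the list alone (adjusted p = 0.462 with an estimated correlation). Complex I genes fell in 1 of 36, Ndufb10 (-0.30 ± 0.072), and 5 fell adjusted over the list alone (adjusted p = 0.462 with an estimated correlation). Mfn1 (-0.45 ± 0.084) and the ADP/ATP carrier Slc25a4 (-0.45 ± 0.10) fell among 28 import and dynamics genes, 2 also adjusted over the list alone. Gpi1, glucose phosphate isomerase, rose by 0.49 ± 0.083, 1 of 18 glycolysis genes (3 adjusted over the list alone, adjusted p = 0.462 with an estimated correlation). Among called genes at or above the median level whose libraries did not overlap, the largest falls were Hist1h4i, a histone H4 gene (-1.69 ± 0.40), Amy1 (-1.67 ± 0.23), Padi2, which converts arginine to citrulline (-1.41 ± 0.32), Lrtm1 (-1.30 ± 0.29), Ctxn3 (-0.91 ± 0.22) and Maob (-0.90 ± 0.22). The largest rises among such genes were Lrp2bp (1.33 ± 0.31), Smtnl2 (1.32 ± 0.26), Ldlrad3 (1.11 ± 0.24), Mybbp1a (0.92 ± 0.21), the small GTPase Rab13 (0.87 ± 0.19) and the mitochondrial ribosome assembly gene Mpv17l2 (0.82 ± 0.15). Camera called 6 lists and none with an estimated correlation. The others were fast contractile (0 of 15 called, 1 rose adjusted over the list alone, adjusted p = 0.462 with an estimated correlation) and antioxidant (0 of 22, 2 fell adjusted over the list alone, adjusted p = 0.462 with an estimated correlation), with ribosomal proteins (0 of 48, 0 adjusted over the list alone, median -0.14, adjusted p = 0.872 with an estimated correlation). After recentring Ndufb10, Slc25a4, Ctxn3 and Maob were not called. In all, 95 genes were called (62 higher, 33 lower; 62 and 20 after recentring). The 6 libraries alone gave 2 genes, and leaving out 1 library gave 25 (without wild-type replicate 2) to 73.

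In soleus of the ERRbeta/ERRgamma class the fall centred on fatty acid and branched-chain amino acid catabolism. Fatty acid oxidation genes fell in 23 of 25 (25 adjusted over the list alone, median -0.73), including Acaa2 (-1.03 ± 0.13), the acyl-CoA synthetase Acsl1 (-1.14 ± 0.17) and Hadhb of the trifunctional protein (-0.91 ± 0.14). Branched-chain amino acid and ketone genes fell in 15 of 19 (17 adjusted over the list alone, median -0.50), including Dbt of the branched-chain dehydrogenase (-0.92 ± 0.13) and the transaminase Bcat2 (-0.75 ± 0.11). Both lists held with an estimated correlation. The respiratory chain moved little: 0 of 36 complex I genes were called (0 adjusted over the list alone, median -0.043, adjusted p = 0.564 with an estimated correlation). Of all, 7 of 76 respiratory chain genes fell, led by Sdhb (-0.51 ± 0.079) and Atp5h (-0.34 ± 0.071). These were 3 of 14 in complexes II and III (3 adjusted over the list alone, adjusted p = 0.382 with an estimated correlation). The others were 1 of 11 in cytochrome c oxidase (1 adjusted over the list alone, adjusted p = 0.511 with an estimated correlation) and 3 of 15 in ATP synthase (5 adjusted over the list alone, adjusted p = 0.382 with an estimated correlation). TCA cycle genes fell in 7 of 23 (16 adjusted over the list alone, adjusted p = 0.255 with an estimated correlation), with Idh2 at -1.20 ± 0.20. Regulators of biogenesis fell in 4 of 20 (1 rose and 6 fell adjusted over the list alone, adjusted p = 0.255 with an estimated correlation). Among them were Ppara, a fatty acid sensing receptor (-0.75 ± 0.17), the mitochondrial DNA packaging factor Tfam (-0.43 ± 0.10) and the ERR-induced regulator Perm1 (-0.73 ± 0.18). Glycolysis genes rose in 5 of 18 (6 adjusted over the list alone, adjusted p = 0.564 with an estimated correlation), with Aldoa at 0.56 ± 0.15, but in 1 of 18 after recentring. Import and dynamics genes fell in 5 of 28 (7 fell adjusted over the list alone, adjusted p = 0.255 with an estimated correlation). Chaperones and proteases fell in 3 of 12 (3 adjusted over the list alone, adjusted p = 0.255 with an estimated correlation), with Clpx at -0.58 ± 0.10. Of fast contractile genes 2 of 15 rose (3 adjusted over the list alone, adjusted p = 0.564 with an estimated correlation), the light chains Myl1 (1.36 ± 0.22) and Mylpf (0.80 ± 0.18). Of satellite cell genes 2 of 10 rose (3 adjusted over the list alone, adjusted p = 0.168 with an estimated correlation), Des (0.61 ± 0.13) and Myf6 (0.76 ± 0.16). No ribosomal protein gene was called (0 of 48, 0 adjusted over the list alone, adjusted p = 0.564 with an estimated correlation).

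Single genes moved further in that comparison. Among called genes at or above the median level whose libraries did not overlap, the largest falls were Lrtm1 (-2.00 ± 0.29), the mitochondrial carrier Slc25a34 (-1.89 ± 0.36), Gmnn (-1.87 ± 0.22), the acyl-CoA thioesterase Acot2 (-1.86 ± 0.44), Dgat2 of triglyceride synthesis (-1.79 ± 0.30) and the desaturase gene Fads6 (-1.57 ± 0.18). The largest rises among such genes were the stress-induced Ankrd1 (3.00 ± 0.56), Rgcc (2.12 ± 0.42), the tendon transcription factor Scx (2.10 ± 0.25), Irf5 (1.68 ± 0.44), the matricellular gene Ctgf (1.55 ± 0.39) and Eda2r (1.55 ± 0.26).

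Some connective tissue genes also rose in that comparison. Fibroblast and matrix genes rose in 4 of 21 (7 adjusted over the list alone, median 1.05, adjusted p = 0.511 with an estimated correlation), including the matrix genes Tnc (3.62 ± 0.93), Postn (2.62 ± 0.72) and Thbs4 (1.75 ± 0.49). Leukocyte markers were called in 0 of 18 (0 adjusted over the list alone, median 1.28, adjusted p = 0.564 with an estimated correlation). The median over both lists against the wild-type mean was 2.34, -0.18 and 1.46 in knockout-labelled replicates 1, 2 and 3, and wild-type replicate 2 lay 1.36 above the other wild types. Of 898 genes called (423 higher, 475 lower), the count was 396 without knockout-labelled replicate 1, 2139 without knockout-labelled replicate 2, 440 without wild-type replicate 3, and 4 in a fit of the 6 libraries alone. Pairs of these knockout-labelled libraries differed with an SD across genes of 0.56 to 0.81, against 0.35 to 0.53 within the other groups. The shared estimate of the spread takes all groups as equal, so the SEs of this comparison may be too small and its calls too many. Without knockout-labelled replicate 1 fatty acid oxidation genes fell in 19 of 25, branched-chain and ketone genes in 7 of 19, and fibroblast genes rose in 0 of 21. Without any 1 of the other libraries these were 21 to 24, 11 to 16 and 0 to 15.

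In soleus of the ERRalpha/ERRgamma class both the respiratory chain and fatty acid oxidation fell. Complex I fell in 28 of 36 (median -0.53), complexes II and III in 14 of 14 (-0.76), cytochrome c oxidase in 10 of 11 (-0.67), and ATP synthase in 13 of 15 (-0.55). The TCA cycle fell in 23 of 23 (-0.71), fatty acid oxidation in 22 of 25 (-0.68) and branched-chain and ketone catabolism in 14 of 19 (-0.51). Adjusted over the list alone the counts were 32, 14, 10, 14, 23, 23 and 17, none rose, and all 7 calls held with an estimated correlation. Ndufab1 was at -1.01 ± 0.065, Sdhb at -1.05 ± 0.079, Cox6b1 at -1.06 ± 0.071, the oxoglutarate dehydrogenase subunit Dlst at -1.22 ± 0.089 and Acaa2 at -1.24 ± 0.13. Mitochondrial ribosome genes fell in 27 of 57 with 1 rise (adjusted over the list alone 1 rose and 30 fell). Import and dynamics genes fell in 20 of 28 (adjusted over the list alone 21 fell), with Mfn1 at -1.46 ± 0.084. Antioxidant genes fell in 9 of 22 with 1 rise (the same adjusted over the list alone), with Sod2 at -1.36 ± 0.089. Chaperones and proteases fell in 7 of 12 with 1 rise (8 and 1 adjusted over the list alone), with Dnaja3 at -0.77 ± 0.07, and held with an estimated correlation. Regulators of biogenesis fell in 4 of 20 with 1 rise (the same adjusted over the list alone, adjusted p = 0.112 with an estimated correlation), with Ppara at -1.06 ± 0.17 and Tfam at -0.53 ± 0.10. Glycolysis genes rose in 7 of 18 (9 adjusted over the list alone, adjusted p = 0.181 with an estimated correlation), including the muscle enolase Eno3 (1.16 ± 0.15) and Aldoa (1.09 ± 0.15). Denervation and atrophy genes rose in 7 of 23 (8 adjusted over the list alone, adjusted p = 0.181 with an estimated correlation), including the developmental myosins Myh8 (3.63 ± 0.56) and Myh3 (2.66 ± 0.54). Ribosomal protein genes rose in 39 of 48 (44 adjusted over the list alone, adjusted p = 0.112 with an estimated correlation) and in 30 of 48 after recentring. Among called genes at or above the median level whose libraries did not overlap, the 6 largest rises were Gamt (2.89 ± 0.43), Sln (2.70 ± 0.62), Actn3 (2.16 ± 0.58), the glycogen-binding Stbd1 (2.16 ± 0.20), Scx (2.13 ± 0.25) and the matrix gene Aebp1 (2.06 ± 0.24). The largest falls among such genes were the magnesium transporter Slc41a1 (-2.18 ± 0.12), Padi2 (-2.10 ± 0.32), Lrtm1 (-2.02 ± 0.29), BC048679 (-2.01 ± 0.41, not called with missing values set to the lowest value), Kcng4 (-1.95 ± 0.46) and the mitochondrial malic enzyme Me3 (-1.95 ± 0.13). Fibroblast and leukocyte markers had medians of 0.36 and 0.75 with 0 of 21 and 0 of 18 called. In all, 1700 genes were called, 915 higher and 785 lower, and 537 and 961 after recentring, the median of all genes being 0.11 above 0.

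**Figure D3:**
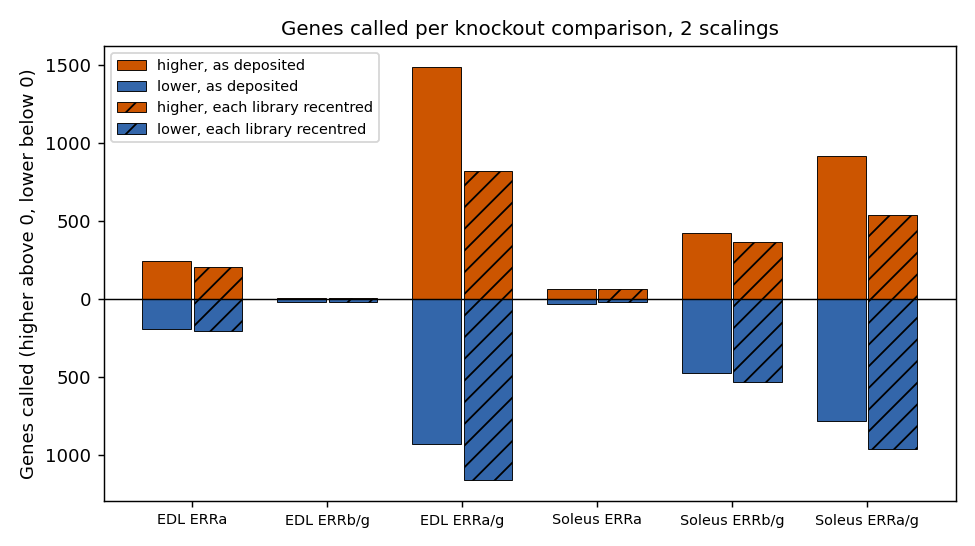
Genes called higher (above 0) and lower (below 0) per knockout comparison (horizontal axis), with the values as deposited and with each library recentred (hatched). The ERRalpha/ERRgamma class had 1487 higher and 929 lower genes in EDL as deposited, and 819 and 1162 after recentring.

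Whether a class acted differently in the 2 muscles was tested with interaction contrasts. In the ERRalpha/ERRgamma class the fall of the respiratory chain was smaller in soleus: 55 of 76 chain genes differed, all in that direction, with a median difference of 0.63. Complexes II and III differed in 13 of 14 genes (14 adjusted over the list alone) and the TCA cycle in 19 of 23 (21 adjusted over the list alone), and both lists held with an estimated correlation. Chchd10 differed by 2.48 ± 0.13, Ndufb5 by 1.42 ± 0.12, Cyc1 by 1.42 ± 0.12, the aspartate transaminase Got2 by 1.51 ± 0.14 and Atp5o by 1.15 ± 0.10. Fatty acid oxidation differed in 1 of 25 genes (7 adjusted over the list alone, adjusted p = 0.446 with an estimated correlation). That contrast called 276 genes (200 higher, 76 lower in soleus minus EDL), and camera called 13 lists, 7 of them with an estimated correlation. Esrra itself fell less in soleus, by a difference of 1.66 ± 0.16. In the ERRalpha class 2 genes differed, Phkb (-2.36 ± 0.21) and Rab15, a small GTPase (-3.18 ± 0.57), and 965 at an unadjusted p under 0.05. In the ERRbeta/ERRgamma class 28 did (7 higher, 21 lower), among them Gmnn (-2.06 ± 0.32), the lymphotoxin receptor Ltbr (0.94 ± 0.16), Tbc1d10b (0.80 ± 0.14), Mospd1 (-0.73 ± 0.13) and the peroxisomal import gene Pex7 (-0.69 ± 0.13). Camera called 13 lists in the ERRalpha class and 12 in the ERRbeta/ERRgamma class, and none of either with an estimated correlation. In the ERRalpha class 0 of 36 complex I genes were called, with all 36 above 0 (12 higher adjusted over the list alone, median 0.21, adjusted p = 0.0842 with an estimated correlation). In the ERRbeta/ERRgamma class 0 of 25 fatty acid oxidation genes were called, with none above 0 (10 lower adjusted over the list alone, median -0.42, adjusted p = 0.613 with an estimated correlation). With the animal as a block the counts of genes were 9 and 107, and in a fit of the contrast's libraries alone limma called 1 and 0. Leaving out 1 library gave 1 to 5 in the ERRalpha class. In the ERRbeta/ERRgamma class it gave 1, 521 and 29 without soleus knockout-labelled replicates 1, 2 and 3, 39, 16 and 3 without soleus wild-type replicates 1, 2 and 3, 12, 3 and 5 without EDL knockout-labelled replicates, and 6, 14 and 7 without EDL wild-type replicates, in the same order.

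Classes were compared within each muscle, each against its own wild types. In EDL the ERRalpha/ERRgamma class differed from the ERRalpha class in 638 genes (177 higher, 461 lower; 91 and 542 after recentring), with all 23 TCA cycle genes lower (23 adjusted over the list alone). Idh3b differed by -1.70 ± 0.094, Sdhb by -1.92 ± 0.11, Cyc1 by -2.09 ± 0.12 and Uqcrc1 by -1.89 ± 0.11. It differed from the ERRbeta/ERRgamma class in 914 genes (374 higher, 540 lower; 250 and 607 after recentring), with 33 of 36 complex I genes lower (35 adjusted over the list alone) and Ndufa8 at -1.92 ± 0.093. The ERRbeta/ERRgamma and ERRalpha classes differed in 55 genes of EDL, with 7 of 36 complex I genes higher in the former (27 adjusted over the list alone), Ndufa13 by 0.79 ± 0.12. Lower there were Phkb (-2.37 ± 0.21), the lactate dehydrogenase Ldhb (-1.70 ± 0.21) and Osbpl3 (-2.38 ± 0.35), and higher was P2ry1, a purine receptor (2.15 ± 0.33). The 55 became 24 in a fit of the contrast's libraries alone, and 35 and 34 without wild-type replicate 1 and knockout-labelled replicate 3 of the ERRbeta/ERRgamma class. Camera called 13, 16 and 10 lists in these 3 contrasts, and 10, 10 and 2 with an estimated correlation. In soleus the ERRalpha/ERRgamma class differed from the ERRalpha class in 635 genes (244 higher, 391 lower; 133 and 541 after recentring), Idh3b by -1.03 ± 0.094, Me3 by -2.01 ± 0.18, Slc41a1 by -1.85 ± 0.18 and the angiogenic factor Vegfb by -1.33 ± 0.13. It differed from the ERRbeta/ERRgamma class in 161 genes (43 higher, 118 lower; 23 and 137 after recentring), with 20 of 36 complex I genes lower (27 adjusted over the list alone), Ndufa8 by -0.89 ± 0.093 and Ndufab1 by -0.82 ± 0.092. Of fatty acid oxidation genes 0 of 25 were called in that contrast (0 adjusted over the list alone). The 161 became 29 in a fit of the contrast's libraries alone and 323 without knockout-labelled replicate 2 of the ERRbeta/ERRgamma class. The ERRbeta/ERRgamma and ERRalpha classes differed in 71 genes of soleus, led by the uracil glycosylase Ung (-2.50 ± 0.33), the lysophospholipid acyltransferase Lpcat3 (-1.22 ± 0.18), Twf2 (-1.08 ± 0.16), Cetn2 (-0.88 ± 0.14) and Fbxo44 (-1.80 ± 0.30). That count was 878 without knockout-labelled replicate 2 of the former, 16 without knockout-labelled replicate 3 of the latter and 1 in a fit of the contrast's libraries alone. Lists called in the 3 soleus contrasts were 15, 12 and 10, and 12, 9 and 0 with an estimated correlation.

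Changes were set side by side across comparisons that share no library. Genes lower in both muscles of the ERRalpha/ERRgamma class numbered 562, where independent lists of that length would share 54.6, and 497 were higher in both, where they would share 102. Across 13342 genes the changes correlated with Pearson's r of 0.43, with genes not being independent replicates and some animals giving both muscles. In EDL the ERRalpha and ERRalpha/ERRgamma classes shared 151 lower genes (13.6 from independent lists) and 157 higher (27.1), and in soleus the ERRbeta/ERRgamma and ERRalpha/ERRgamma classes shared 263 lower (27.9) and 167 higher (28.9). The numbers for independent lists take every gene as equally likely to be called. All comparisons used the same estimate of each gene's spread, and knockout-labelled libraries of every class carry Cre, so the excess does not measure receptor action alone. Sets of 200 genes that separated wild-type muscles of the other 2 classes were also followed, and camera called 9 of 12 tests of them at the preset correlation. In EDL of the ERRbeta/ERRgamma class 10 of the 200 soleus genes fell and 0 rose (median -0.14, adjusted p = 0.0785 with an estimated correlation). In soleus of that class 51 fell and 15 rose (median -0.18, adjusted p = 0.370 with an estimated correlation). Of the soleus genes 26 rose and 4 fell in EDL of the ERRalpha class (median 0.13, adjusted p = 0.527 with an estimated correlation), and in its soleus 4 of the EDL genes rose and 0 fell (median 0.11, adjusted p = 0.451 with an estimated correlation). In EDL of the ERRalpha/ERRgamma class 44 of the soleus genes rose and 50 fell, while 50 of the EDL genes rose and 4 fell (medians -0.0047 and 0.20, adjusted p = 0.544 with an estimated correlation for both). In its soleus 16 of the soleus genes rose and 53 fell, while 56 of the EDL genes rose and 6 fell (medians -0.048 and 0.27, adjusted p = 0.451 with an estimated correlation for both). The other call was for the EDL genes in EDL of the ERRbeta/ERRgamma class (1 rose, 0 fell, median 0.061, adjusted p = 0.676 with an estimated correlation). No call held with an estimated correlation.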

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

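The tests on Esrra, Esrrb, matched genes, marker genes of other cells and the share of connective tissue RNA were chosen after the results were seen. So were the splits that take account of the animal and the second draw of splits. The interaction and class contrasts, recentring and other splits were planned.

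The results below stand out because a contrast tested the difference between 2 groups' changes and called it. Between muscles (soleus minus EDL) 2 genes differed in the ERRalpha class, 28 in the ERRbeta/ERRgamma class and 276 in the ERRalpha/ERRgamma class. First by adjusted p were Phkb (-2.36) and Rab15 (-3.18), then Gmnn (-2.06) and Ltbr (0.94), then Chchd10 (2.48) and Ndufb5 (1.42). Between classes in EDL 638 genes differed for ERRalpha/ERRgamma minus ERRalpha (Chchd10 -2.70, Idh3b -1.70), 914 for ERRalpha/ERRgamma minus ERRbeta/ERRgamma (Chchd10 -2.72, Ndufa8 -1.92) and 55 for ERRbeta/ERRgamma minus ERRalpha (Phkb -2.37, Ldhb -1.70). In soleus the same 3 differences called 635 genes (Idh3b -1.03, Me3 -2.01), 161 genes (Ndufa8 -0.89, Ndufab1 -0.82) and 71 genes (Ung -2.50, Lpcat3 -1.22).

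Respiratory chain genes fell more in EDL than in soleus of the ERRalpha/ERRgamma class, with a median difference of 0.63 over 76 genes. A shift of whole libraries does not account for it, since the median was 0.65 after each library was recentred. Recentring cannot test an effect of quantile normalization that varies with level. Esrrb was 3.85 higher in knockout-labelled soleus than in knockout-labelled EDL of that class, so a part played by ERRbeta in soleus cannot be told apart from other differences between the muscles, which no library separates from it. The same holds for a weaker fall of the Esrra signal in soleus, which need not measure the deletion. That signal changed by -0.57 ± 0.12 in soleus against -2.23 ± 0.12 in EDL, a difference of 1.66 ± 0.16. The difference in fibre type between the muscles also stays open, untested.

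Ribosomal protein genes rose in the ERRalpha/ERRgamma class, in 46 of 48 in EDL and 39 in soleus. A shift of whole libraries alone does not account for this, since 43 and 30 rose after recentring. Recentring takes the same amount off every gene of a library, so it cannot test an effect of quantile normalization that varies with level. RNA from leukocytes or fibroblasts would raise their markers. In EDL the median of 39 of them was 0.093 (95% bootstrap interval over marker genes -0.089 to 0.16), below the ribosomal median of 0.50. That interval leaves out the spread between animals, so the values argue against such RNA in EDL without ruling it out. In soleus such RNA cannot be told apart from a change of this group, because the markers' median was 0.60 (0.36 to 0.71) against a ribosomal median of 0.39. A trend with level or length stays open too, since the ribosomal median in EDL lay only 0.15 above that of genes matched for level and exon length (0.35). A biological change of ribosomal protein genes stays open.

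Connective tissue and leukocyte genes in soleus of the ERRbeta/ERRgamma class had a median change of 1.17 over 39 genes, with 4 of 21 and 0 of 18 called higher, and neither list held with an estimated correlation. Without knockout-labelled replicate 1 the median was 0.65 and 0 genes were called, so the part of 1 library cannot be told apart with 3 per group. A share of such RNA that varied between libraries fits, since wild-type replicate 2 lay 1.36 above the other wild types. A lower share of muscle fibres alone would raise vessel markers alike, but their median lay 1.33 below (-1.33, 95% bootstrap interval over marker genes -1.59 to -1.02). That interval leaves out the spread between animals, so with 3 libraries per group a lower share of muscle fibres is not ruled out. A change brought by the deletion stays open.

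Other splits of the libraries into groups of the same sizes were run over 11914 genes with a value in all libraries. For differences between muscles or classes, the fitted terms for muscle or class and for genotype were first subtracted, also for the real count. The values left over were regrouped there, not the values as measured. For a knockout comparison only 10 splits exist, too few to show an effect, since the share of splits as large cannot be under 0.05. Counts at least as large came in 1 of 10 splits for EDL of the ERRalpha class (439 real, 2 the highest other), the ERRbeta/ERRgamma class (25 and 0) and the ERRalpha/ERRgamma class (2425 and 2). They came in 1 of 10 for soleus of the ERRalpha class (98 and 7), in 2 of 10 for the ERRbeta/ERRgamma class (915 and 1008) and in 1 of 10 for the ERRalpha/ERRgamma class (1727 and 2). The split with 1008 put knockout-labelled replicates 1 and 3 with wild-type replicate 2, the libraries highest in connective tissue and leukocyte genes. Splits that involve both muscles took account of the animal, as read from the column names. For wild-type soleus against EDL, muscle marks were swapped within an animal and those of lone libraries shuffled. The count was 1 of 100 (6913 real, 5586 the highest other). For the differences between muscles, genotype marks were moved between animals, the same in both muscles. By the reading of the column names all 6 animals of the ERRalpha and ERRbeta/ERRgamma classes gave both muscles. Again only 10 splits exist there, too few for a share under 0.05, with 1 of 10 in each (2 and 0, 28 and 2). In the ERRalpha/ERRgamma class, with 2 such animals, the count was 1 of 52 splits (282 and 46). That is the smallest share these splits can give, and shares were not adjusted over contrasts, so chance is unlikely there but not excluded. For the differences between classes in EDL the count was 1 of 100 for ERRalpha/ERRgamma minus ERRalpha (650 and 231). It was 2 of 100 for ERRalpha/ERRgamma minus ERRbeta/ERRgamma (955 and 1055) and 1 of 100 for ERRbeta/ERRgamma minus ERRalpha (58 and 7). In soleus, in the same order, it was 1 of 100 (658 and 45), 2 of 100 (173 and 341) and 7 of 100 (100 and 448). A second draw, run only for the last, gave 4 of 100 (highest other 368), so chance is not excluded for it either.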

How the results depend on the processing

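The animal block and missing values set to the lowest value were chosen after seeing the data, and all other alternatives were planned, but the library singled out in soleus of the ERRbeta/ERRgamma class was picked afterwards. The planned replicate-number block was not run for counts or gene lists, since the columns carry no replicate numbers. The animal served as replicate block instead, pairing the muscles of 14 of 22 animals. With it the difference between muscles called 9 genes in the ERRalpha class and 107 in the ERRbeta/ERRgamma class, and no other count moved by over 1.5 times. Recentring moved no total of genes called by over 1.5 times, but it took the genes called higher from 1487 to 819 in EDL ERRalpha/ERRgamma, from 915 to 537 in soleus ERRalpha/ERRgamma and from 177 to 91, 244 to 133 and 43 to 23 in EDL ERRalpha/ERRgamma minus ERRalpha and soleus ERRalpha/ERRgamma minus ERRalpha and minus ERRbeta/ERRgamma, and those lower from 33 to 20 in soleus ERRalpha. A minimum of 1.5-fold left 219, 1114, 56, 498 and 770 genes in EDL ERRalpha, EDL ERRalpha/ERRgamma, soleus ERRalpha, soleus ERRbeta/ERRgamma and soleus ERRalpha/ERRgamma, 3205 between wild-type muscles, and 414 and 100 for soleus ERRalpha/ERRgamma minus ERRalpha and minus ERRbeta/ERRgamma, through its own construction. With only the samples of the contrast, the spread came from fewer libraries and from those groups alone. Counts were 201 in EDL ERRalpha, 4 in EDL ERRbeta/ERRgamma, 2 in soleus ERRalpha and 4 in soleus ERRbeta/ERRgamma. Equally small fits called 2158 genes in EDL and 1404 in soleus of the ERRalpha/ERRgamma class, so fewer libraries need not be the whole cause. In the same setting the differences between muscles called 1 (ERRalpha) and 0 (ERRbeta/ERRgamma). Between classes it gave 24 for EDL ERRbeta/ERRgamma minus ERRalpha, 29 for soleus ERRalpha/ERRgamma minus ERRbeta/ERRgamma and 1 for soleus ERRbeta/ERRgamma minus ERRalpha. The 2 genes of the difference between muscles in the ERRalpha class became 1 with no filter on low values, with only genes above the median level, with a pseudocount and without the trend, and 5 with missing values set to the lowest value. That of the ERRbeta/ERRgamma class became 46 above the median level and 14 without the trend, and soleus ERRbeta/ERRgamma minus ERRalpha 123 and 37. Gene lists called fell to 5, 0, 0, 2 and 11 with an estimated correlation in EDL ERRalpha, EDL ERRbeta/ERRgamma, soleus ERRalpha, soleus ERRbeta/ERRgamma and soleus ERRalpha/ERRgamma, and to 8, 0, 0 and 9 with fry in the first 4 of these, while muscle-type lists fell from 9 to 0 with an estimated correlation. Leaving out 1 library at a time gave these ranges of genes called: 225 to 303 in EDL ERRalpha, 11 to 25 in EDL ERRbeta/ERRgamma, 1871 to 2014 in EDL ERRalpha/ERRgamma, 25 to 73 in soleus ERRalpha, 396 to 2139 in soleus ERRbeta/ERRgamma and 1234 to 1436 in soleus ERRalpha/ERRgamma. For differences between muscles they were 1 to 5 (ERRalpha), 1 to 521 (ERRbeta/ERRgamma, lowest without knockout-labelled soleus replicate 1, highest without replicate 2) and 199 to 255 (ERRalpha/ERRgamma). For EDL they were 476 to 638 for ERRalpha/ERRgamma minus ERRalpha, 757 to 893 for ERRalpha/ERRgamma minus ERRbeta/ERRgamma and 34 to 55 for ERRbeta/ERRgamma minus ERRalpha. For soleus they were 485 to 657 for ERRalpha/ERRgamma minus ERRalpha, 122 to 323 for ERRalpha/ERRgamma minus ERRbeta/ERRgamma and 16 to 878 for ERRbeta/ERRgamma minus ERRalpha, the last 2 highest without knockout-labelled replicate 2 of the ERRbeta/ERRgamma class. Lists called ranged from 9 to 13 in EDL ERRalpha, 6 to 10 in EDL ERRbeta/ERRgamma, 15 to 16 in EDL ERRalpha/ERRgamma, 5 to 10 in soleus ERRalpha, 11 to 16 in soleus ERRbeta/ERRgamma and 18 to 20 in soleus ERRalpha/ERRgamma. Esrra, not called in EDL of the ERRbeta/ERRgamma class, turned from -0.022 to 0.056 without wild-type replicate 2, with a range of -0.11 to 0.056 over the libraries left out. Over the 363 changes of named genes, 4716 values under an alternative were the same, 526 weaker, 10 stronger and 1 reversed. A value was the same where it kept its direction and stayed called or stayed not called. With only the samples of the contrast, 231 of the 363 were the same and 132 weaker. Where no construction is given, the cause was not tested. Depth per library is unknown, and genes with few reads, seen as steps of whole reads, were often missing, which limits calls at low levels.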

Other observations

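The angiogenic factor gene Vegfb fell in 4 of the 6 knockout comparisons: by 1.84 ± 0.091 in EDL and 1.44 ± 0.091 in soleus of the ERRalpha/ERRgamma class, 0.61 ± 0.091 in EDL of the ERRalpha class and 0.64 ± 0.091 in soleus of the ERRbeta/ERRgamma class. In EDL of the ERRalpha/ERRgamma class Vegfa fell by 0.46 ± 0.15 and Angpt1 rose by 0.42 ± 0.15, so 2 of 12 angiogenic genes fell and 1 rose (the same adjusted over the list alone), the rise not being called after recentring. In soleus of that class Fgf1 changed by -0.66 ± 0.19 and Pdgfa by 0.35 ± 0.11, again with 2 falls and 1 rise (the same adjusted over the list alone), and again the rise was not called after recentring. In soleus of the ERRalpha class Pdgfa changed by 0.48 ± 0.11. Endothelial markers fell in 3 of 16 in EDL of the ERRalpha/ERRgamma class (6 after recentring, 6 adjusted over the list alone, adjusted p = 0.204 with an estimated correlation): the growth factor receptors Flt1 (-0.63 ± 0.13) and Kdr (-0.60 ± 0.17) and Eng (-0.58 ± 0.20). They fell in 1 of 16 in soleus (1 adjusted over the list alone, adjusted p = 0.27 with an estimated correlation), Tie1 (-0.43 ± 0.11). Regulators of biogenesis fell in 4 of 20 in EDL of that class with 1 rise (the same adjusted over the list alone), with Ppara at -1.64 ± 0.17, Perm1 at -0.95 ± 0.18 and Tfb2m at -0.71 ± 0.069. Camera did not call the list (adjusted p = 0.16).

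Car3 rose in 5 of the 6 comparisons, from 1.21 ± 0.28 in soleus of the ERRbeta/ERRgamma class to 2.49 ± 0.28 in EDL of the ERRalpha/ERRgamma class. It was the only fat cell marker of 12 that rose in any of them, while Lipe fell in that EDL (-0.72 ± 0.22). In the ERRalpha/ERRgamma class the immediate early gene Jun rose in EDL (0.86 ± 0.11) and soleus (0.83 ± 0.11), 1 of 15 each (1 and 6 adjusted over the list alone, the soleus list being lost at adjusted p = 0.197 with an estimated correlation). The clock gene Cry2 rose in EDL (0.69 ± 0.14, 3 of 15 clock genes, 1 after recentring, 4 adjusted over the list alone) and soleus (0.52 ± 0.14, 1 of 15, 4 adjusted over the list alone), and Nr1d2 fell in soleus of the ERRbeta/ERRgamma class (-0.39 ± 0.091). Of Schwann cell markers, Ngfr rose in EDL (3.28 ± 0.80) and Mbp, a myelin protein, fell in soleus (-1.77 ± 0.54) of the ERRalpha/ERRgamma class, 1 of 12 each, also adjusted over the list alone (soleus list adjusted p = 0.408 with an estimated correlation). Integrated stress genes went both ways: Cth fell by 1.79 ± 0.28 and Mthfd2 rose by 1.19 ± 0.34 in soleus of the ERRbeta/ERRgamma class (1 and 1 of 22, 1 and 3 adjusted over the list alone). Atf5 fell in the ERRalpha class in EDL (-0.49 ± 0.14) and soleus (-0.66 ± 0.14). Among smooth muscle and pericyte markers Cspg4 rose in soleus of the ERRbeta/ERRgamma class (1.05 ± 0.30) and Kcnj8 fell in soleus of the ERRalpha/ERRgamma class (-0.67 ± 0.22), 1 of 11 each (1 and 0 adjusted over the list alone).

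A hypothesis was tested that the receptors act together on the respiratory chain by more than the sum of the separate classes, a contrast chosen after the class results were seen. The ERRalpha/ERRgamma change minus the ERRalpha change minus the ERRbeta/ERRgamma change had a median of -0.98 over 76 respiratory chain genes in EDL. Of these, 61 were called lower and 0 higher (-1.02 and 62 after recentring). In soleus the median was -0.39, with 24 lower. Fatty acid oxidation genes gave -0.58 in EDL (6 of 25 lower) and 0.027 in soleus (0 called). The sum of the 2 changes as measured does not account for the values of the respiratory chain in EDL. A weaker deletion in the ERRalpha class would leave the same excess. Esrra there changed by -0.19 ± 0.12 in EDL and 0.33 ± 0.12 in soleus, neither called, against -2.23 ± 0.12 in EDL of the ERRalpha/ERRgamma class. Signals over a whole gene need not show the loss of 1 exon, so these values do not measure how strong a deletion was. The classes pair different receptors, ERRbeta being named in 1 of them only, and each has its own wild-type littermates, so an action of ERRalpha with ERRgamma stays a hypothesis found and tested on the same data.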
